A study of Mus musculus with 16 samples.

How the data were processed

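RNA-seq libraries of sorted mouse megakaryocyte-erythroid progenitors were labelled as 4 groups of 4, crossing Calr genotype (wild-type, WT, or heterozygous mutant, called mutant here) with vehicle or 2-deoxyglucose (2-DG). Of these 16 libraries, 15 had values and 1 WT 2-DG library was not analysed here. The labels give each mouse's sex but not if a library came from 1 mouse or pooled mice, so gene p-values measure the spread between libraries.

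Per the labels' protocols, RNA was isolated from sorted cells with PicoPure kits, cDNA was made with SMART-Seq v4 and libraries with Swift 2S Plus, and the sequencing was stranded. Per the submitters' processing notes, which name tools without their roles or order, FastQC 0.11.9, MultiQC 1.10.1, STAR 2.7.9a, HTSeq 0.12.4, DESeq2 1.30.1 and the genome build GRCm39 were used. The authors deposited a table of 21886 genes whose unit is a normalised signal, read counts divided by 1 size factor per library. In every library the values were whole multiples of 1 step, and division by that step gave whole reads for 100% of the values within 0.001 read. The reciprocal of the step differed from DESeq2's median-of-ratios size factor by a relative difference of at most 4e-06. Size factors lay between 0.714 and 1.36, and the recovered libraries held 27.72 to 53.27 M reads assigned to genes.

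The test fixed before the data were examined for normalised values was limma 3.58.1 (R 4.3.3), with a trend and robust moderation, on log2(value + 1). Genes with a value of at least 10 in at least 4 libraries were tested (15482 genes). A single fit held all 15 libraries with group and sex as terms, p-values were two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 within its comparison. Differences are on the log2(value + 1) scale, which understates changes of low genes. There were 5 planned comparisons: mutant against WT under vehicle and under 2-DG, 2-DG against vehicle in each genotype, and the difference between the 2-DG effects of the 2 genotypes. Another 2 comparisons, the mean 2-DG effect over both genotypes and the mean mutant effect over both treatments, were added after the data were seen, when limma had called 0 genes in the 5 planned ones. edgeR 4.0.16 (quasi-likelihood, TMM) and DESeq2 1.42.0 were run on the recovered reads as alternatives.

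The 34 gene lists, the alternatives and the rule for named genes were also fixed before the data were examined. The lists included markers of other cells that the sort could hold. limma's camera tested each list against the spread across genes at a preset inter-gene correlation of 0.01, adjusted over the 34 lists per comparison, and again with an estimated correlation. The score of a list in a library is the mean of its members' log2 values, each centred on its gene. Exact two-sided permutation tests of the group difference in these scores, with sex kept as a term, relabelled the libraries of the compared groups (70 relabelings for 4 against 4, 35 for 4 against 3 and 2450 for the 2-DG effect within both genotypes), adjusted over the lists in the same way. The smallest p that 70 relabelings gave was 0.0286.

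Per comparison, the named genes are the 10 higher and 10 lower genes with the largest log2 difference among those called with a mean of at least 50 in the higher group, leaving out predicted models, pseudogenes, Y-linked genes, Xist and Tsix. Where fewer than 10 passed, the genes with the smallest unadjusted p filled the places and are given as values only. Up to 4 members per list with the smallest p, and a fixed set of focus genes, were also named. The lists described were chosen after the data were seen: those whose call held in each of the 15 fits that left out 1 library and, where called, the N-glycosylation list, lists of other cells and mitochondrially encoded transcripts. JAK-STAT targets in WT cells, interferon-stimulated genes under vehicle and a few lists that did not pass are given beside them, and the other called lists as counts, except that all are given for the difference of effects. Some genes that these rules took are not reported here.

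The library titles carry the prefixes SX, RB, GG or TT, whose meaning the labels do not give, treated as possible batches. WT vehicle held 3 SX libraries and 1 RB, WT 2-DG 2 SX and 1 TT, mutant vehicle 1 GG and 3 RB, and mutant 2-DG 2 GG and 2 RB. Mutant 2-DG and WT 2-DG share no prefix, so no value within a prefix exists for them. Values within a prefix are differences of mean log2 values without a sex term, so sex can contribute to them. Alternatives were other pseudocounts and filters, TMM scaling, a fit without sex, with the prefix as a term, with array quality weights or with only the compared groups, edgeR, DESeq2, an estimated correlation, and each library left out in turn. After the data were seen, a correction for transcript length and GC content and a fit with a neutrophil marker score as a term were added. Length and GC came from an annotation of another build (GRCm38) through gene symbols, for 15029 tested genes (97.1%).

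The procedure was tested on simulated reads drawn from the means and library sizes, with 200 genes changed. limma found 23.9% (difference of effects) to 71.6% (mutant effect over both treatments) of genes changed 1.5-fold. For 2-fold it found 55.2% (difference of effects) to 88.1% (both averaged comparisons). For 4-fold it found 80.3% (2-DG in WT cells) to 95.5% (mutant effect over both treatments). False calls in the 7 comparisons numbered 7 to 12 with limma, 5 to 11 with edgeR and 19 to 40 with DESeq2. Real libraries hold structure that the groups do not follow, so their rates can differ. The 21 library pairs within groups differed by a chi-square per gene of 13 to 53.4, far beyond counting noise. No library appeared to be a copy.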

Results

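Transcript levels were measured by RNA-seq in megakaryocyte-erythroid progenitors, the cells that give rise to megakaryocytes and red cells, sorted from mice as lineage-negative, Sca-1-negative and c-Kit-positive with low CD34 and Fc gamma receptor. The mice carried MxCre, a recombinase transgene that pIpC switches on, with wild-type Calr (WT) or with 1 mutant allele that the labels write as CalrD52/+ and, in the genotype field, as Calr fl/+ (mutant). Calr encodes calreticulin, a calcium-binding chaperone of the endoplasmic reticulum (ER) that helps N-glycosylated proteins to fold. Starting 2 weeks after induction the mice received vehicle or 750 mg/kg of 2-deoxyglucose (2-DG) by intraperitoneal injection for 18 days. 2-DG is a glucose and mannose analogue that interferes with glycolysis and with N-glycosylation, the pathway that the study's title names in CALR-mutant myeloproliferative neoplasm. Library depths, in M reads assigned to genes, were 39.28, 37.18, 39.82 and 47.57 in WT vehicle 1 to 4 and 51.27, 34.41 and 34.76 in WT 2-DG 1 to 3. They were 51.91, 38.32, 36.86 and 35.94 in mutant vehicle 1 to 4, and 27.72, 53.27, 39.36 and 29.28 in mutant 2-DG 1 to 4.

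Calr itself was abundant in each group, at a normalised read count of 36217 ± 2226 (SD, n = 4) in WT vehicle, 41194 ± 1252 (n = 3) in WT 2-DG, 34945 ± 2202 (n = 4) in mutant vehicle and 33630 ± 3240 (n = 4) in mutant 2-DG. These gene totals cannot separate mutant from wild-type transcripts and so do not check the genotype labels. Of the sex genes, the Y-linked Ddx3y was listed at 0 in each of the 7 libraries labelled female, at 1389.1 in WT vehicle 2 and at 3039 to 3547.6 in the other 7. Globin genes (Hbb-bt, Hba-a2), replication-dependent histone genes (H3c4, H3c6) and ribosomal protein genes have near-identical copies or pseudogenes between which the authors' counting could split reads, so their values are less certain.

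Mutant against WT progenitors under vehicle asked what the Calr mutation does without drug. ER chaperone genes were higher in mutant cells: 24 of the 29 tested members of the list of ER chaperones and targets of the stress regulators ATF6 and XBP1 lay above WT, with a median log2 difference of 0.122, or 8.79% (adjusted p = 0.129 with an estimated correlation). Its members with the smallest p were the protein disulfide isomerases Pdia4, at 0.31 ± 0.07 (log2 difference ± SE), and Pdia6, at 0.25 ± 0.07, and the ERAD ubiquitin ligase Syvn1, at 0.24 ± 0.06. The N-glycosylation list, which holds the enzymes that build the lipid-linked glycan and the oligosaccharyltransferase (OST) that transfers it, was higher by a smaller amount, with 33 of 40 members above WT and a median of 0.0598, or 4.23% (adjusted p = 0.129 with an estimated correlation). It was led by the OST subunits Rpn1 (0.18 ± 0.05) and Tusc3 (0.16 ± 0.07) and the glucosyltransferase Alg8 (0.16 ± 0.06). Genes of red cell maturation were higher as well, with medians of 0.11 for erythroid genes (26 of 30 members above WT, adjusted p = 0.697 with an estimated correlation) and 0.113 for heme synthesis and iron handling (19 of 20, adjusted p = 0.639 with an estimated correlation).

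The ER chaperone list passed camera at an adjusted p of 6.13e-10 and the N-glycosylation list at 4.66e-06. Their scores were higher in all 4 mutant libraries than in any of the 4 WT libraries (exact permutation p = 0.0286, adjusted p = 0.486). Over all genes 0 members of either list were called, whereas 6 ER chaperone members and 0 N-glycosylation members were higher when adjusted over the list alone. In the RB libraries alone (1 WT against 3 mutant) the medians were 0.142 and 0.0442. With a prefix term they were 0.13, past the threshold, and 0.0284, no longer past it. The secretion and ER translocation list, with 29 of 44 members higher and a median of 0.0475, also passed (adjusted p = 0.00131, or p = 0.468 with an estimated correlation). Of its members 0 passed adjusted over the list alone or over all genes. Its scores lay above the WT mean in 4 of 4 mutant libraries, with a median of 0.0553 among RB libraries, and it no longer passed at 0.0383 with a prefix term.

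The erythroid list had an adjusted p of 1.37e-05 and the heme list one of 7.92e-05. In each, 4 of 4 mutant scores lay above the WT mean and 0 members passed over all genes or adjusted over the list alone. Markers of mature red cells and reticulocytes, which the Ter119 gate should remove, moved with them: 14 of 16 were higher, with a median of 0.29 and of 0.379 among RB libraries. They passed at an adjusted p of 3.27e-06 in 4 of 4 libraries (adjusted p = 0.468 with an estimated correlation). The globin Hbb-bt (0.73 ± 0.20) was the 1 member higher adjusted over the list alone, against 0 over all genes. Among RB libraries the erythroid median was 0.0101 and the heme median 0.0676. With a prefix term they were −0.0276 and −0.00378. Without WT vehicle 1 the erythroid and heme medians were 0.0589 and 0.0493, and without mutant vehicle 1 they were 0.0465 and 0.0563, still past the threshold. The erythroid median was 0.168 without mutant vehicle 2. Lymphoid and plasma cell markers (lymphoid markers) had a median of 0.462, and of 0.827 among RB libraries, with 15 of 19 members and 3 of 4 libraries higher and 0 members past either threshold (adjusted p = 0.0131, or p = 0.793 with an estimated correlation). That call was lost without WT vehicle 3 or 4 (0.434, 0.121) or mutant vehicle 1 or 2 (0.412, 0.178) and with a neutrophil score term (0.402), and the median was 0.814 without WT vehicle 1, 0.889 without mutant vehicle 3 and 1.13 with a prefix term. Interferon-stimulated genes were called as higher (median 0.215, 34 of 43 members, 3 of 4 libraries, adjusted p = 0.00291, or p = 0.838 with an estimated correlation) with 0 members past either threshold. They stood at −0.324 among RB libraries and passed as lower with a prefix term (−0.347, adjusted p = 6.12e-06). Their call was lost without WT vehicle 2 (0.134) or mutant vehicle 3 (−0.0425), and the median was 0.552 without WT vehicle 4 and 0.357 without mutant vehicle 1. Neutrophil markers did not pass (median 0.291, 16 of 24 members, 2 of 4 libraries, adjusted p = 0.413, 0.358 among RB libraries). They passed as higher with a prefix term (1.55) and without WT vehicle 1 (0.695) or mutant vehicle 3 (0.869), and as lower without WT vehicle 4 (−0.432) or mutant vehicle 1 (−0.318).

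Gene by gene, limma called 0 genes between mutant and WT under vehicle, with a smallest adjusted p of 1. At an unadjusted p under 0.05 there were 465, fewer than the 774 expected by chance. With edgeR the count was also 0. DESeq2 called 2, the disulfide isomerase Pdia3 and the pseudogene Ncoa4-ps, named here after their values were seen. Pdia3 had the smallest limma p, at 0.28 ± 0.05 with all 4 mutant libraries above every WT library, and lay 0.383 higher among RB libraries. Other named genes on the higher side included the histone gene H3c4 (0.62 ± 0.14) and the insulin receptor substrate Irs2 (0.68 ± 0.16). On the lower side Sec16a of ER exit sites stood at −0.24, and each had an adjusted p of 1. All 20 named genes kept their sign among RB libraries. Calr differed by −0.05 ± 0.07. In all, 12 lists were called, each as higher, of which 10 kept their sign among RB libraries, 6 their call in each of the 15 fits without 1 library and 3 with a prefix term, where 1 was called as lower.

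**Figure D1:**
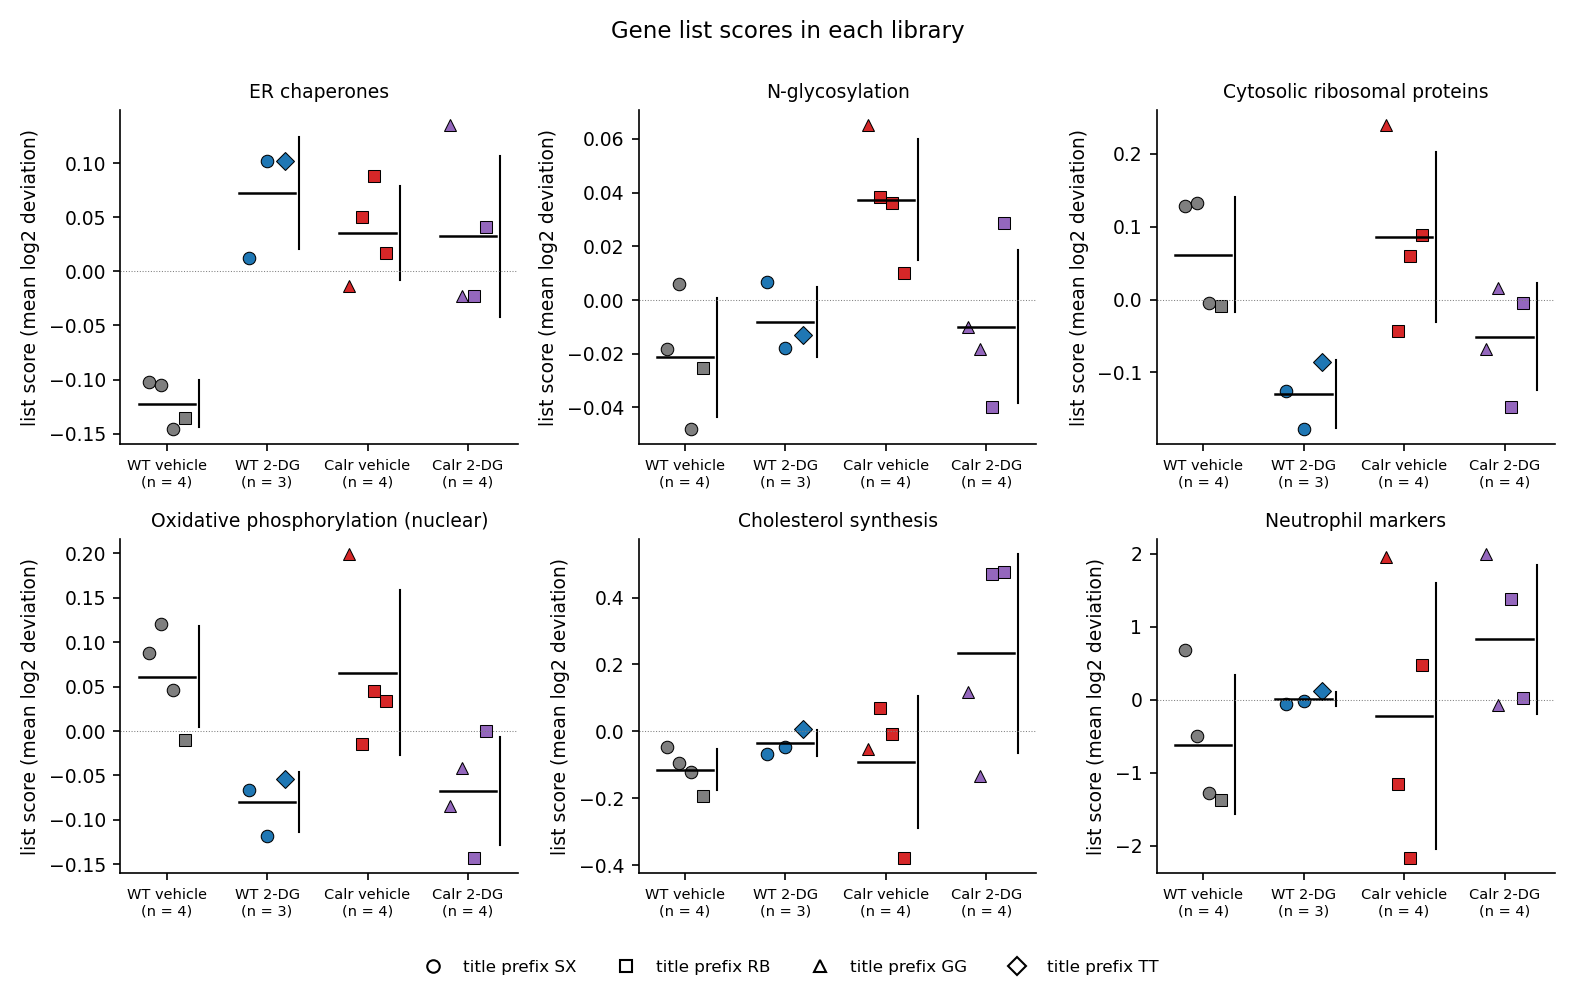
Score of 6 gene lists in each library (mean log2 value of the members, each gene centred on its mean; points are libraries with the marker giving the title prefix, lines are group means and bars 1 SD; n = 4 per group, 3 in WT 2-DG). ER chaperone scores in all 4 mutant vehicle and all 3 WT 2-DG libraries lie above those of the 4 WT vehicle libraries.

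2-DG against vehicle in mutant progenitors asked what the drug does to the mutant cells. Ribosomal, oxidative phosphorylation, cell cycle and red cell lists were lower under 2-DG and cholesterol synthesis, JAK-STAT and glycolysis lists higher, each with an adjusted p = 0.35 with an estimated correlation. All 48 cytosolic ribosomal protein genes and all 44 nuclear genes of oxidative phosphorylation had negative differences, each list with a median of −0.128, or −8.52%. The G2-M list (35 of 37 members lower, median −0.154), the S phase list (32 of 34 lower, −0.0898), erythroid genes (27 of 30 lower, −0.246) and heme genes (16 of 20 lower, −0.174) moved the same way. Genes of cholesterol synthesis were higher (21 of 22, median 0.306, or 23.6%), led by Cyp51 (0.46 ± 0.12), Idi1 (0.35 ± 0.09) and the SREBP regulator Insig1 (0.43 ± 0.12). Targets of JAK-STAT signalling, a pathway downstream of cytokine receptors, were higher in 18 of 23 members with a median of 0.3, among them the feedback inhibitors Socs3 (2.78 ± 0.72) and Socs2 (1.89 ± 0.52) and Myc (0.23 ± 0.06). Glycolysis genes were higher in 22 of 26 members with a median of 0.139, led by phosphofructokinase Pfkp (0.78 ± 0.20) and hexokinase Hk2 (0.98 ± 0.27).

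These lists passed camera with adjusted p-values of 6.45e-14 (ribosomal), 8.9e-14 (oxidative phosphorylation), 3.1e-12 (G2-M), 3.02e-06 (S phase), 1.24e-09 (erythroid and cholesterol), 0.000147 (heme), 0.000265 (JAK-STAT) and 0.000341 (glycolysis). Scores lay on the side of the change from the vehicle mean in 4 of 4 mutant 2-DG libraries for each of them except cholesterol synthesis, with 3 of 4. Over all genes 0 members were called in any list. Adjusted over the list alone, 13 members of the G2-M list were lower (the cyclin Ccnb2 −0.35 ± 0.09), and 13 of cholesterol synthesis and 7 of the JAK-STAT list were higher. Of glycolysis 2 were higher and 1 lower, 1 erythroid gene was lower (the globin Hba-a2, −1.46 ± 0.37), and 0 ribosomal, oxidative phosphorylation, S phase or heme genes passed. Among RB libraries (3 vehicle, 2 2-DG) and among GG libraries (1 vehicle, 2 2-DG) the medians were −0.105 and −0.273 for ribosomal genes, −0.096 and −0.261 for oxidative phosphorylation, −0.158 and −0.205 for G2-M, and −0.0814 and −0.139 for S phase. They were −0.108 and −0.508 for erythroid genes and −0.0754 and −0.384 for heme genes. Of the lists that were higher, the medians were 0.542 and 0.0478 for cholesterol synthesis, 0.308 and 0.393 for JAK-STAT targets, and 0.0906 and 0.162 for glycolysis. Without mutant vehicle 1 the ribosomal median was −0.0807, without mutant vehicle 2 the S phase median was −0.136, and without mutant vehicle 3 the JAK-STAT median was 0.497, all past the threshold.

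Markers of other cells moved in the same comparison. Mature red cell markers were lower in 14 of 16 members and 4 of 4 libraries, with a median of −0.471, and of −0.256 among RB and −0.687 among GG libraries (adjusted p = 1.24e-09, or p = 0.35 with an estimated correlation). Adjusted over the list alone 10 of them were lower (the mitophagy receptor Bnip3l −0.25 ± 0.07), against 0 over all genes. Neutrophil and granulocyte markers, which the Gr-1 and CD11b gates should remove, were higher in 24 of 24 members with a median of 0.92 in 4 of 4 libraries (adjusted p = 0.000147, or p = 0.512 with an estimated correlation). They lay at 1.53 among RB but at −1.27 among GG libraries. That median was 1.61 without mutant vehicle 1, and 0.314 and no longer past the threshold without mutant vehicle 3. It was 1.46 without mutant 2-DG 2, 0.558 without mutant 2-DG 3, 0.541 with edgeR and 0.579 with DESeq2. Monocyte, macrophage and dendritic cell markers (monocyte markers) had a median of 0.757, with 18 of 20 members and 3 of 4 libraries higher (adjusted p = 0.00169, or p = 0.436 with an estimated correlation). Their median was 1.27 among RB and 0.865 among GG libraries. It was 0.47 without mutant vehicle 1, 1.22 without mutant 2-DG 2 and lost its call without mutant 2-DG 3 (0.277). Lymphoid markers were higher in 17 of 19 members with a median of 0.78 in 4 of 4 libraries (adjusted p = 0.000147, or p = 0.35 with an estimated correlation). The median was 0.259 among RB and 0.776 among GG libraries and 0.369 without mutant vehicle 3. In these 3 lists 0 members passed over all genes or adjusted over the list alone.

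Immediate early genes, which also respond to handling of cells, were higher in 19 of 19 members with a median of 0.42 in 4 of 4 libraries (adjusted p = 1.18e-05, or p = 0.35 with an estimated correlation). That median was 0.323 among RB and 0.511 among GG libraries, 0.255 without mutant 2-DG 3 and 0.699 without mutant 2-DG 4. Of them Junb (0.36 ± 0.11), Zfp36 (1.17 ± 0.36) and Fosl2 (1.22 ± 0.40) passed adjusted over the list alone and 0 over all genes. Inflammation and NF-kB genes were higher in 15 of 17 members with a median of 0.438 in 4 of 4 libraries (adjusted p = 0.000341, or p = 0.35 with an estimated correlation). Of them 0 passed either threshold. Their median was 0.62 among RB and 0.283 among GG libraries. It was 0.217 without mutant vehicle 3, 0.223 without mutant 2-DG 3, 0.287 with edgeR and 0.285 with DESeq2, past the threshold in each. Mitochondrially encoded transcripts, listed beforehand as a sign of RNA quality, were lower in 11 of 11 members with a median of −0.117, in 2 of 4 libraries and with 0 members past either threshold (adjusted p = 0.0222, or p = 0.512 with an estimated correlation). The median was −0.154 among RB and −0.135 among GG libraries. The call was lost without mutant vehicle 1 (−0.0754) or mutant 2-DG 3 (−0.0169), with array weights (−0.0884) and with the length and GC correction (−0.086). The N-glycosylation list was slightly lower, with 11 of 40 members above vehicle and a median of −0.0513, or −3.49%, in 4 of 4 libraries (adjusted p = 0.0191, or p = 0.35 with an estimated correlation). Its median was −0.03 among RB and −0.0872 among GG libraries, and 0 members passed either threshold. This call was lost without mutant vehicle 1 (−0.0354), mutant 2-DG 2 (−0.0455) or mutant 2-DG 3 (−0.0471) and with array weights (−0.0439), and the median was −0.0321 with the length and GC correction. The ER chaperone list did not pass (median −0.0317, 11 of 29 higher, adjusted p = 0.38, 2 of 4 libraries below the vehicle mean). Its median was −0.0774 among RB and 0.114 among GG libraries. It passed as lower without mutant 2-DG 1 (−0.0753), and the median was 0.0365 without mutant 2-DG 3.

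For single genes in mutant cells under 2-DG limma called 0, with 2101 at an unadjusted p under 0.05. edgeR called 0, and DESeq2 called 235, 126 higher and 109 lower. Named values on the higher side included Fam124a (2.27 ± 0.43), the fractalkine receptor Cx3cr1 (1.73 ± 0.33) and the cell cycle inhibitor Cdkn1a (1.47 ± 0.28). On the lower side Arrdc4, an arrestin-domain gene whose transcription follows intracellular glucose, stood at −1.33 ± 0.22. All 20 named genes kept their sign among RB and among GG libraries. The count was 7 without WT 2-DG 1, 13 without mutant vehicle 2 and 2 without mutant 2-DG 2 (Arrdc4 among them). Calr differed by −0.06 ± 0.07. In all 10 lists were called as higher and 11 as lower, of which 13 kept their call in each fit without 1 library and 20 with a prefix term.

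2-DG against vehicle in WT progenitors asked the same of cells without the mutation. Ribosomal protein genes were lower here too, in 47 of 48 members with a median of −0.217, or −14% (adjusted p = 0.368 with an estimated correlation), led by the acidic stalk proteins Rplp2 (−0.27 ± 0.07) and Rplp1 (−0.31 ± 0.08). Oxidative phosphorylation genes were lower in 39 of 44 members (median −0.124, adjusted p = 0.373 with an estimated correlation). ER chaperones were higher in 25 of 29 members with a median of 0.176, or 13% (adjusted p = 0.368 with an estimated correlation), led by Pdia4 (0.34 ± 0.08), Hyou1 (0.35 ± 0.10) and Sdf2l1 (0.40 ± 0.12). Genes of the integrated stress response, the ATF4 and CHOP programme of amino acid supply, were higher in 24 of 31 members (median 0.206, adjusted p = 0.368 with an estimated correlation), with the amino acid transporter Slc7a5 at 0.32 ± 0.09 and the folate enzyme Mthfd2 at 0.46 ± 0.15. Genes of N-glycan trimming and the calnexin-calreticulin cycle were higher in 20 of 29 members (median 0.12, adjusted p = 0.368 with an estimated correlation), among them the folding sensor Uggt1 (0.16 ± 0.06) and the mannosidase-like Edem1 (0.20 ± 0.07).

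The camera adjusted p-values were 2.69e-29 for ribosomal genes, 5.48e-14 for oxidative phosphorylation, 1.85e-07 for ER chaperones, 0.000337 for the integrated stress response and 0.000782 for N-glycan trimming. Scores lay on the side of the change in 3 of 3 WT 2-DG libraries for all 5 lists. The exact permutation p was 0.0286 for ER chaperones (adjusted p = 0.324), the smallest that 35 relabelings gave. Over all genes 0 members were called, and adjusted over the list alone 36 ribosomal and 6 oxidative phosphorylation genes were lower, 5 ER chaperones were higher, and 0 integrated stress response or N-glycan trimming genes passed. Among SX libraries (3 vehicle, 2 2-DG) the medians were −0.246, −0.178, 0.157, 0.171 and 0.101 in the order of the adjusted p-values above, and with the length and GC correction the oxidative phosphorylation median was −0.0787, past the threshold.

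Glycolysis genes were higher in 22 of 26 members and 3 of 3 libraries, with a median of 0.178, and of 0.122 among SX libraries (adjusted p = 7.81e-05, or p = 0.368 with an estimated correlation). Of them 0 passed either threshold. The median was 0.0926 without WT vehicle 4, still past the threshold, and 0.0798 with a prefix term, no longer past it. Cholesterol synthesis genes were higher in 19 of 22 members and 3 of 3 libraries, with a median of 0.174, and of 0.0558 among SX libraries (adjusted p = 0.000366, or p = 0.503 with an estimated correlation). This median was 0.295 without WT 2-DG 1 and 0.103 without a sex term, where it no longer passed. JAK-STAT targets were higher in 16 of 23 members and 2 of 3 libraries, with a median of 0.0832, and of 0.13 among SX libraries (adjusted p = 0.0338, or p = 0.479 with an estimated correlation). Socs2 was the 1 member higher adjusted over the list alone. The call was lost without WT vehicle 2 or 3 (0.121, 0.051), WT 2-DG 2 or 3 (0.0651, 0.0131), mutant vehicle 1 (0.0774) or mutant 2-DG 1 or 3 (0.104, 0.0753), with a prefix term (0.0561), with only the compared groups (0.0498) and with the length and GC correction (0.0698). The median was 0.132 without WT vehicle 4, 0.287 without WT 2-DG 1 and 0.163 without a sex term. Erythroid genes were lower in 27 of 30 members and 2 of 3 libraries, with a median of −0.24 (adjusted p = 1.41e-06, or p = 0.503 with an estimated correlation). Their median was −0.23 among SX libraries, −0.456 without WT 2-DG 1 and −0.0845 without WT 2-DG 2. Mature red cell markers were lower in 13 of 16 members and 2 of 3 libraries, with a median of −0.241, and of −0.308 among SX libraries (adjusted p = 0.00332, or p = 0.557 with an estimated correlation). The call was lost without WT 2-DG 2 (−0.121). Bnip3l (−0.32 ± 0.08) was the 1 member of that list lower adjusted over the list alone. Lymphoid markers were higher in 17 of 19 members and 3 of 3 libraries, with a median of 0.971 (adjusted p = 3.76e-06, or p = 0.373 with an estimated correlation). That median was 0.724 among SX libraries, 0.592 without WT vehicle 4 and 0.476 with a prefix term. Adjusted over the list alone 0 members of the cholesterol, erythroid or lymphoid lists passed, and over all genes 0 members of any list. Mitochondrially encoded transcripts were lower in 10 of 11 members and 3 of 3 libraries, with a median of −0.222 and 4 members past the threshold adjusted over the list alone (adjusted p = 3.3e-06, or p = 0.373 with an estimated correlation). Their median was −0.232 among SX libraries, −0.142 without WT 2-DG 2 and −0.141 without a sex term. The N-glycosylation list did not pass (median 0.0324, 24 of 40 higher, adjusted p = 0.285, 3 of 3 libraries above the vehicle mean, 0.0489 among SX libraries). Its OST subunit Tmem258 (−0.31 ± 0.07) was lower adjusted over the list alone.

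limma called 0 genes for 2-DG in WT cells, with 1467 at an unadjusted p under 0.05 and a smallest adjusted p of 0.206. The edgeR count was 0 and the DESeq2 count 47, 22 higher and 25 lower. Named values on the higher side included Fam124a (2.97 ± 0.49), Plek2, a pleckstrin family gene induced by erythropoietin signalling (2.62 ± 0.44), Socs2 (2.87 ± 0.59) and Irs2 (1.01 ± 0.18). On the lower side the ATP synthase inhibitor Atpif1 stood at −0.40 ± 0.09. All 20 named genes kept their sign among SX libraries, and the count was 7 without WT 2-DG 1. Calr differed by 0.19 ± 0.08. In all 8 lists were called as higher and 7 as lower, of which 14 kept their sign among SX libraries, and 10 their call in each fit without 1 library and 10 with a prefix term.

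**Figure D2:**
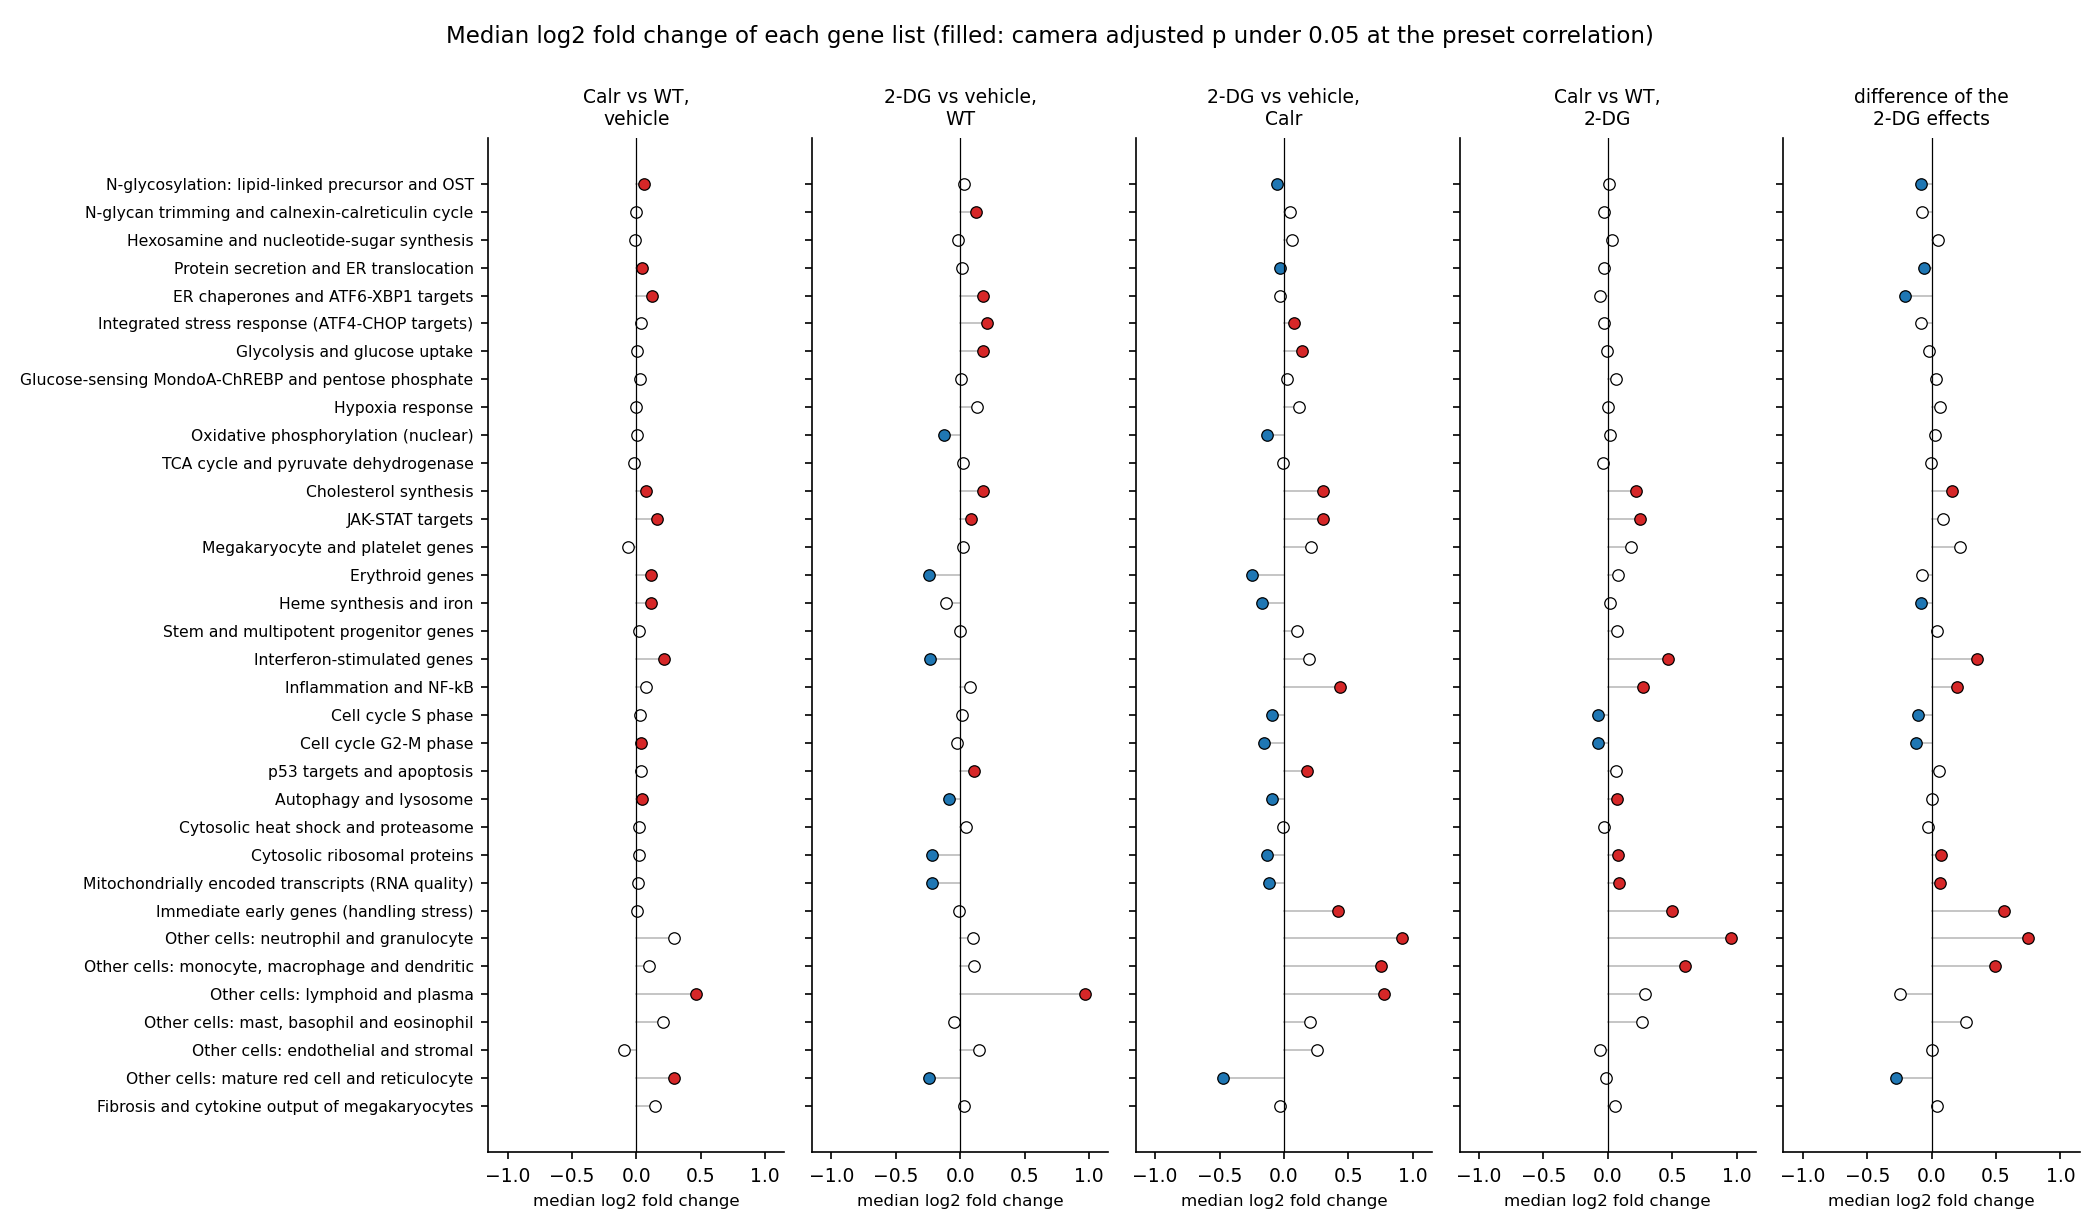
Median log2 difference of the members of each of the 34 gene lists in the 5 planned comparisons (columns), with filled points for lists with a camera adjusted p under 0.05 and open points for the others. Ribosomal protein genes lie at −0.128 in mutant and −0.217 in WT cells under 2-DG.

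The difference between the 2 drug effects (2-DG effect in mutant minus 2-DG effect in WT) tested directly whether the genotypes responded unequally. ER chaperones differed most clearly: 26 of 29 members had a less positive 2-DG effect in mutant cells, with a median of −0.208 (adjusted p = 0.181 with an estimated correlation), and the ER chaperones Hsp90b1 (−0.40 ± 0.14) and Hspa5, also called BiP (−0.37 ± 0.14), led the list. The N-glycosylation list differed in the same direction by a median of −0.0799, with 33 of 40 members negative (adjusted p = 0.444 with an estimated correlation), led by Tusc3 (−0.22 ± 0.10) and Rpn1 (−0.15 ± 0.07). The ER list passed camera at an adjusted p of 4.74e-10 and the N-glycosylation list at 0.000362. Over all genes or adjusted over the list alone 0 members of either passed. Both kept their call in each of the 15 fits without 1 library and with a prefix term (−0.164 and −0.112). No prefix holds all 4 groups, so no value within a prefix can be had.

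Another 13 lists were called for this difference, each with an adjusted p of 0.674 or 0.694 with an estimated correlation and each lost in at least 1 fit without 1 library. For single genes limma, edgeR and DESeq2 called 0, with 388 at an unadjusted p under 0.05 and a smallest adjusted p of 1 with limma.

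Mutant against WT progenitors under 2-DG showed interferon-stimulated genes higher in 40 of 43 members with a median of 0.467, or 38.2% (adjusted p = 0.584 with an estimated correlation), led by Ly6e (0.37 ± 0.08) and tetherin Bst2 (0.66 ± 0.24). JAK-STAT targets were higher in 20 of 23 members (median 0.248, adjusted p = 0.383 with an estimated correlation), including Myc (0.25 ± 0.07). So were immediate early genes in 19 of 19 members (median 0.499, adjusted p = 0.566 with an estimated correlation) and ribosomal protein genes in 45 of 48 (median 0.0828, adjusted p = 0.619 with an estimated correlation). The adjusted p-values were 2.72e-13 for interferon-stimulated genes, 1.36e-05 for JAK-STAT targets, 3.2e-08 for immediate early genes and 4.13e-08 for ribosomal genes. Scores lay above the WT 2-DG mean in 4 of 4 mutant libraries, and for ribosomal genes in 3 of 4. Ly6e was the 1 interferon gene higher adjusted over the list alone, against 0 over all genes, and 0 members of the other 3 lists passed either way. The 2 groups share no title prefix, and with a prefix term, which can use the vehicle libraries only, the interferon median was −0.192 and no longer higher, and the ribosomal median 0.138. The interferon median was 0.755 without mutant 2-DG 1 and 0.853 with a neutrophil score term, and the JAK-STAT median 0.152 without WT 2-DG 1 and 0.502 without WT 2-DG 3, all past the threshold. The immediate early median was 0.196 without WT 2-DG 1, 0.274 without mutant 2-DG 3 and 0.317 with array weights, and the ribosomal median 0.0442 with the length and GC correction, all past the threshold.

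Neutrophil markers moved with these lists, with a median of 0.955 in 24 of 24 members and 3 of 4 libraries (adjusted p = 3.28e-05, or p = 0.629 with an estimated correlation). That median was 0.618 without mutant 2-DG 1, 1.48 without mutant 2-DG 2 and 2.59 with a prefix term. Monocyte markers stood at 0.603 in 18 of 20 members and 3 of 4 libraries (adjusted p = 0.00021, or p = 0.587 with an estimated correlation). They lost their call without WT 2-DG 1 (0.0937) or mutant 2-DG 3 (0.168) and with a prefix term (0.732), and lay at 0.934 without WT 2-DG 2, 1.13 without mutant 2-DG 2 and 0.293 with array weights. Mitochondrially encoded transcripts stood at 0.0831 (10 of 11 higher, adjusted p = 0.00245, or p = 0.619 with an estimated correlation, 3 of 4 libraries). Their median was 0.134, −0.00337 and 0.142 without WT 2-DG 1, 2 and 3, and 0.0225, 0.0608, 0.169 and 0.0506 without mutant 2-DG 1, 2, 3 and 4, with no call as higher without WT 2-DG 2 or mutant 2-DG 2. That call was also lost with a prefix term (0.107), and the median was 0.0526 without a sex term. For single genes limma called 0, with 850 at an unadjusted p under 0.05 and a smallest adjusted p of 0.802. The edgeR count was 0 and the DESeq2 count 13, 9 higher and 4 lower. Named values included the erythroid factor Nfe2 (0.27 ± 0.06) and the ubiquitin ligase Mid1 (3.60 ± 0.82) on the higher side. On the lower side were Aknad1 (−2.10 ± 0.43) and Calr itself (−0.30 ± 0.08, adjusted p = 0.887). In all 10 lists were called as higher and 2 as lower, of which 5 kept their call in each fit without 1 library and 5 with a prefix term.

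Averaging the 2-DG effects over both genotypes, a comparison added after the data were seen, gave the only gene calls made with limma: 55 genes rose and 48 fell among the 7 libraries with 2-DG and 8 with vehicle. Among the genes that rose most were the little-studied C2cd4a (4.19 ± 0.79), Podxl, which encodes the sialomucin podocalyxin (3.49 ± 0.67, or 11.2-fold) and the T cell receptor gamma constant gene Trgc1 (2.65 ± 0.49). Others were Fam124a (2.62 ± 0.33), the STAT-induced cytokine inhibitor Socs2 (2.38 ± 0.39) and Plek2 (2.07 ± 0.29). The largest falls were in the glucose-responsive arrestin-domain genes Arrdc4 (−1.14 ± 0.17) and Txnip (−0.88 ± 0.15). Also called were Pfkp (0.75 ± 0.15), Cdkn1a (1.04 ± 0.21), Irs2 (0.82 ± 0.12), the iron hormone erythroferrone Erfe (1.59 ± 0.32) and the mevalonate enzyme Idi1 (0.33 ± 0.07). Of these and other called genes Irs2, Cdkn1a, Erfe and Cx3cr1 were named after their values were seen.

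limma's adjusted p was 0.0138 for Fam124a and 0.0492 for Podxl. With edgeR 111 genes were called, 94 of them shared with limma, and with DESeq2 1148, of which 101 were shared. The count was 9 without a filter and 13 with the length and GC correction, all of them shared. In 19 of the 20 named genes all 7 2-DG libraries lay beyond the vehicle mean of their genotype. All 103 genes had the same sign within the RB (2 2-DG, 3 vehicle), GG (2 and 1) and SX (2 and 3) libraries. They were chosen on these libraries, and median ratios to the pooled difference were 0.775, 1.38 and 1.06. All 103 kept their sign and an unadjusted p under 0.05 with a prefix term, but 0 were called.

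The count of 103 changed with each library left out, and the sign of the 20 named genes with none. It was 2, 0, 10 and 5 without WT vehicle 1, 2, 3 and 4, and 1108, 0 and 1 without WT 2-DG 1, 2 and 3. For the mutant libraries it was 0, 459, 4 and 1 without mutant vehicle 1, 2, 3 and 4 and 5, 247, 4 and 0 without mutant 2-DG 1, 2, 3 and 4. A named gene passed in 3 to 11 of those 15 fits, with Fam124a in 11.

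**Figure D3:**
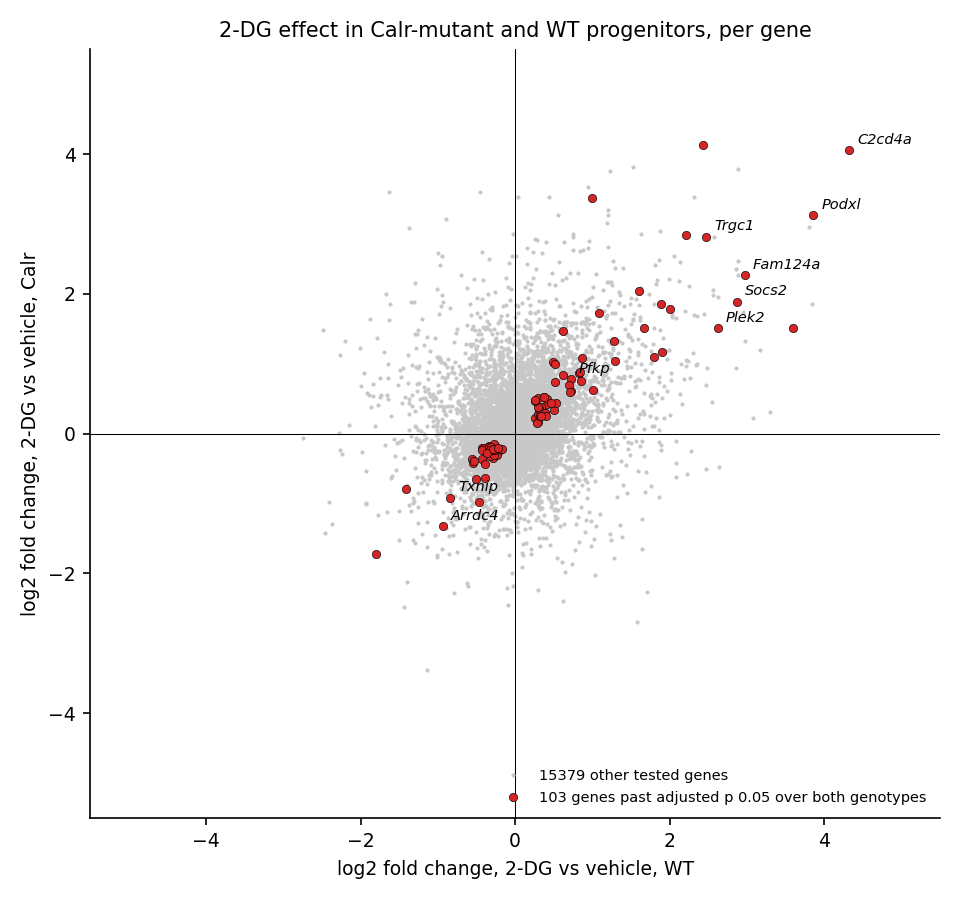
Log2 difference of 2-DG against vehicle in mutant cells (vertical axis) against that in WT cells (horizontal axis), with each point a gene: 103 genes called for 2-DG over both genotypes in colour and 15379 other tested genes in grey. All 103, called on the mean effect, share a sign in both genotypes.

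**Figure D4:**
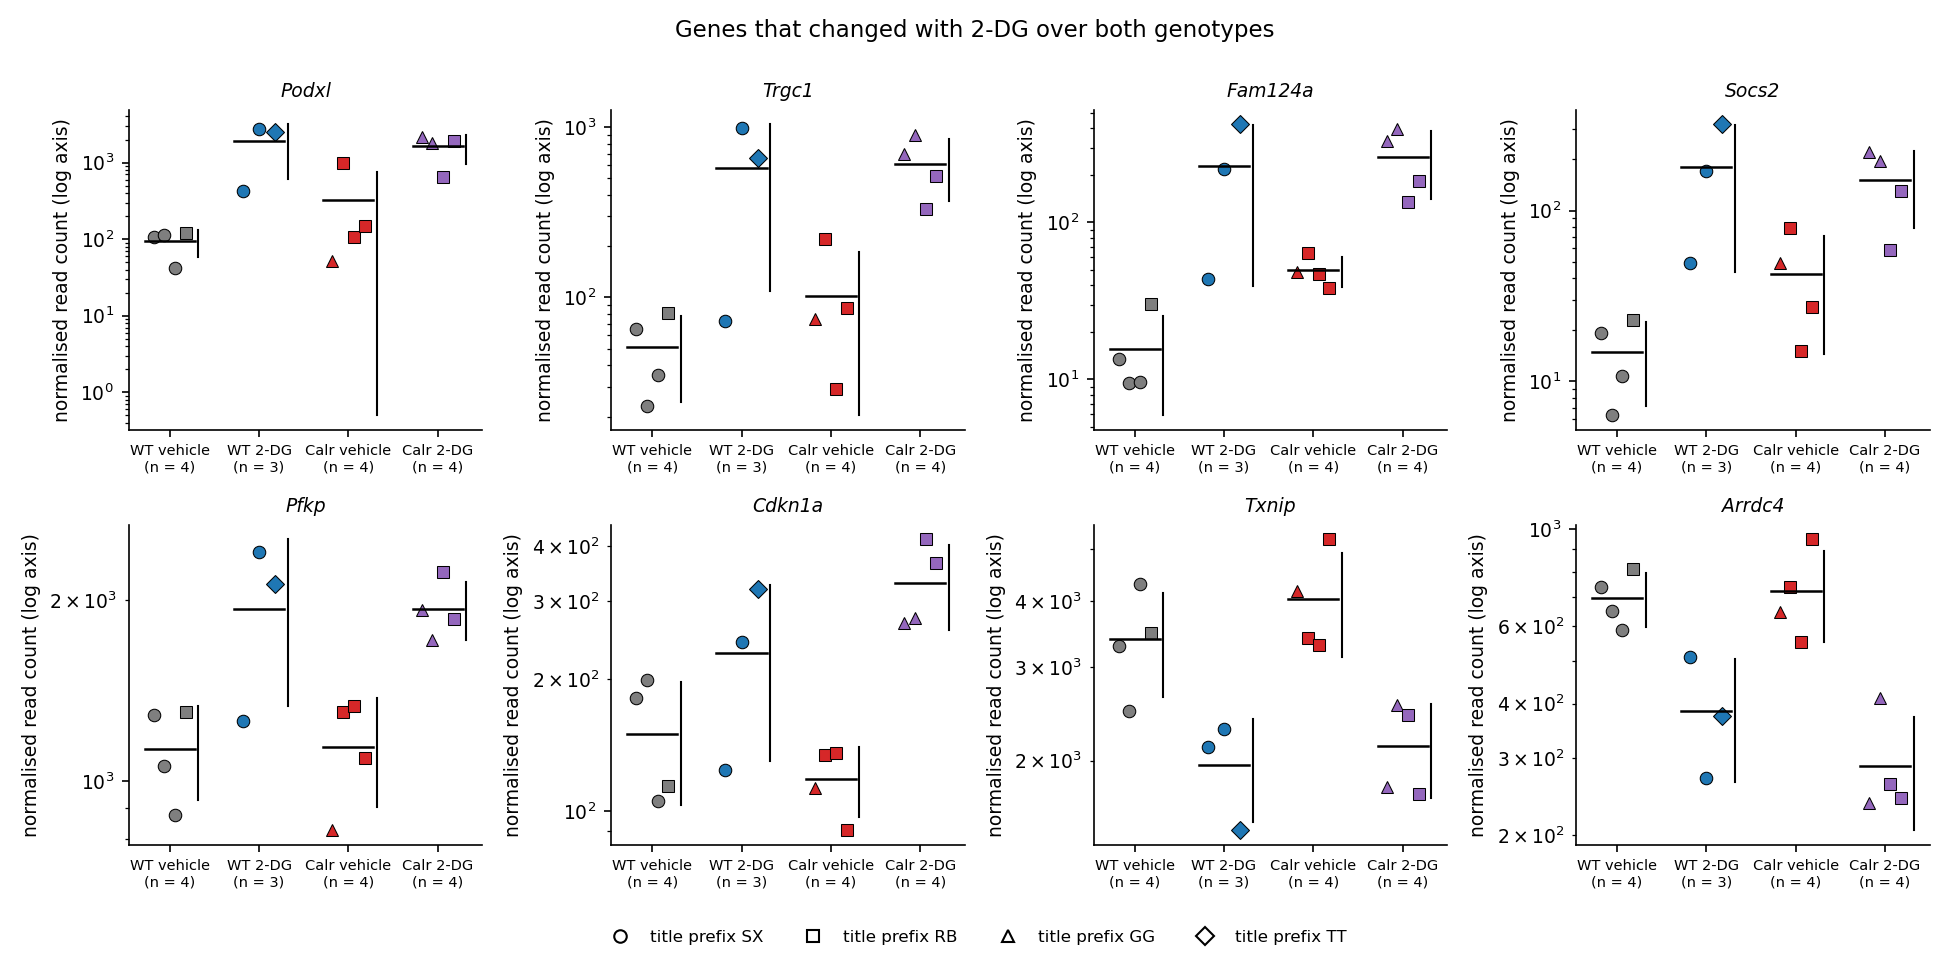
Normalised read count (log axis) of Podxl, Trgc1, Fam124a, Socs2, Pfkp, Cdkn1a, Txnip and Arrdc4 in each library, with group means as lines and 1 SD as bars (n = 4, and 3 in WT 2-DG). Txnip averages 3390 and 4029 in the vehicle groups and 1964 and 2128 in the 2-DG groups.

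Over both genotypes the ribosomal and oxidative phosphorylation lists were lower and the integrated stress response, glycolysis, cholesterol synthesis and JAK-STAT lists higher, each with an adjusted p = 0.287 with an estimated correlation. The ribosomal list had a median of −0.179, with 47 of 48 members and 7 of 7 libraries with 2-DG below vehicle (adjusted p = 3.76e-26). Of these 44 passed adjusted over the list alone and 1, Rplp2 at −0.24 ± 0.05, over all genes. The oxidative phosphorylation list had a median of −0.119, 44 of 44 members and 7 of 7 libraries (adjusted p = 1.32e-17). Here 21 members passed adjusted over the list alone and 3 over all genes, the cytochrome c oxidase subunits Cox6b1 at −0.28 ± 0.05 and Cox6a1 at −0.29 ± 0.06, and Ndufb9 at −0.26 ± 0.06. The integrated stress response list had a median of 0.154 and 24 of 31 members above vehicle, and with all 7 2-DG scores above every vehicle score of their genotype (adjusted p = 0.00106). Adjusted over the list alone 7 members were higher, among them the serine synthesis enzyme Phgdh (0.42 ± 0.10), and 1, the translation repressor Eif4ebp1 (−0.30 ± 0.08), was lower, with 0 over all genes. The glycolysis list had a median of 0.167, 22 of 26 members and 7 of 7 libraries (adjusted p = 1.73e-05). Of them 8 were higher and 1 lower adjusted over the list alone, and 1, Pfkp, passed over all genes. The cholesterol synthesis list had a median of 0.238, 21 of 22 members and 6 of 7 libraries (adjusted p = 4.62e-08), with 11 members higher adjusted over the list alone and 1, Idi1, over all genes. The JAK-STAT list had a median of 0.187, 19 of 23 members and 6 of 7 libraries (adjusted p = 0.00119). The kinase Pim1 (0.73 ± 0.18) and cyclin Ccnd2 (0.64 ± 0.16) were among the 8 higher adjusted over the list alone, and Socs2 was the 1 over all genes. The JAK-STAT median was 0.11 without WT vehicle 4, 0.123 without mutant 2-DG 3 and 0.119 at a filter of 50, past the threshold in each.

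The N-glycan trimming list was higher, with a median of 0.0998, 22 of 29 members and 7 of 7 libraries (adjusted p = 0.00582, or p = 0.316 with an estimated correlation), with 7 members higher adjusted over the list alone and 0 over all genes. Its median was 0.0608 without WT 2-DG 3, 0.0646 without mutant vehicle 1, 0.0565 with a prefix term and 0.0563 without a sex term. ER chaperones had a median of 0.0666 in 21 of 29 members and 5 of 7 libraries (adjusted p = 0.0109, or p = 0.405 with an estimated correlation). Of them 4 were higher and 1 lower adjusted over the list alone and 0 over all genes, and the list no longer passed with a prefix term (0.0473). The erythroid list was lower in 29 of 30 members, with a median of −0.251 (adjusted p = 1.97e-10, or p = 0.316 with an estimated correlation). Heme genes were lower in 15 of 20, with −0.143 (adjusted p = 0.00221, or p = 0.461 with an estimated correlation). G2-M genes were lower in 34 of 37, with −0.0961 (adjusted p = 5.16e-07, or p = 0.394 with an estimated correlation), each of these lists in 6 of 7 libraries. Adjusted over the list alone 11 erythroid, 5 heme and 6 G2-M members were lower, and over all genes only Ccnb2 of G2-M (−0.32 ± 0.07) was. The glucose-sensing list, targets of MondoA and ChREBP with the pentose phosphate pathway, did not pass camera (adjusted p = 0.783). Its median was 0.0335 (7 of 13 higher) and its mean −0.109, and it had Arrdc4 and Txnip lower over all genes and 4 members each way adjusted over the list alone. Its score differed between 2-DG and vehicle in the exact permutation test (p = 0.000408, adjusted p = 0.0139), as did those of the integrated stress response (adjusted p = 0.0278), oxidative phosphorylation (adjusted p = 0.0463), JAK-STAT, N-glycan trimming and p53 target lists (adjusted p = 0.0444 for these 3). In all 12 lists were called as higher and 9 as lower, of which 15 kept their call in each fit without 1 library and 19 with a prefix term.

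Beside these, mature red cell markers were lower in 15 of 16 members and 6 of 7 libraries, with a median of −0.287 (adjusted p = 2.79e-07, or p = 0.287 with an estimated correlation). Of them 10 passed adjusted over the list alone and 1, Bnip3l at −0.29 ± 0.05, over all genes. Lymphoid markers were higher in 18 of 19 members and 7 of 7 libraries, with a median of 0.879 (adjusted p = 9.33e-07, or p = 0.287 with an estimated correlation). The natural killer receptor Ncr1, at 2.69 ± 0.60, was the 1 member higher adjusted over the list alone, against 0 over all genes. Mitochondrially encoded transcripts were lower in 11 of 11 members and 5 of 7 libraries, with a median of −0.188 (adjusted p = 5.35e-05, or p = 0.319 with an estimated correlation), with 6 lower adjusted over the list alone and 0 over all genes. Neutrophil markers had a median of 0.562 in 24 of 24 members and 7 of 7 libraries, 0 members past either threshold (adjusted p = 0.00609, or p = 0.717 with an estimated correlation). That call was lost without WT vehicle 4 (0.175), WT 2-DG 1 (0.464), mutant vehicle 3 (0.299) or mutant 2-DG 3 (0.308), with a prefix term (0.26), with edgeR (0.208) and with DESeq2 (0.222). The neutrophil median was 0.967 without mutant vehicle 1. Monocyte markers stood at 0.452 in 18 of 20 members and 5 of 7 libraries (adjusted p = 0.0256, or p = 0.665 with an estimated correlation). This call was lost without WT vehicle 2 or 3 (0.331, 0.398), WT 2-DG 2 (0.326) or mutant 2-DG 3 (0.12), at a filter of 50 (0.452) and with a neutrophil score term (0.488), the median was 0.799 without WT 2-DG 1, and 0 members passed either threshold.

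The mutant effect averaged over both treatments, also added after the data were seen, gave 0 calls with limma (924 genes at an unadjusted p under 0.05, smallest adjusted p 0.252), 0 with edgeR and 30 with DESeq2 (21 higher, 9 lower). The leading values were in the histone genes H3c6 (0.69 ± 0.12) and H3c4 (0.57 ± 0.10), Mid1 (3.03 ± 0.55) and Myc (0.20 ± 0.05) on the higher side and Sec16a (−0.25 ± 0.05) on the lower. The count was 7 without WT vehicle 4 and 1 without WT 2-DG 1 (Amigo2, named after its value was seen). JAK-STAT targets were higher in 21 of 23 members and 8 of 8 libraries, with a median of 0.205, and of 0.124 without WT 2-DG 1 (adjusted p = 4.24e-07, or p = 0.16 with an estimated correlation). Interferon-stimulated genes were higher in 38 of 43 members and 7 of 8 libraries, with a median of 0.302, and of 0.46 without WT vehicle 4 (adjusted p = 3.15e-12, or p = 0.501 with an estimated correlation). In each list 1 member was higher adjusted over the list alone, Myc and Ly6e (0.26 ± 0.06), against 0 over all genes. With a prefix term the JAK-STAT median was 0.105, no longer past the threshold, and the interferon list passed as lower (−0.207, adjusted p = 0.0347). Cholesterol synthesis genes (22 of 22 members and 6 of 8 libraries, median 0.147, adjusted p = 1.04e-07), immediate early genes (18 of 19, 5 of 8, 0.238, 3.14e-05) and autophagy and lysosome genes (25 of 32, 7 of 8, 0.0441, 0.000992) were called as higher, each with an adjusted p = 0.501 with an estimated correlation. So were ribosomal genes (44 of 48, 5 of 8, 0.0523, adjusted p = 6.24e-06, or p = 0.55 with an estimated correlation), and adjusted over the list alone 0 members of these 4 lists passed. With a prefix term the cholesterol and autophagy medians were 0.0851 and −0.00887, no longer past the threshold, and the ribosomal median 0.103. The immediate early median was 0.149 without mutant vehicle 2. The autophagy median was 0.0242 without WT vehicle 1, 0.0744 without WT 2-DG 1, 0.024 and 0.0665 without mutant vehicle 1 and 2 and 0.0689 without mutant 2-DG 1. The ribosomal median was 0.0238 without WT vehicle 4 and 0.0277 without mutant vehicle 1, both past the threshold. The N-glycosylation list stood at 0.0395 (28 of 40, 5 of 8 libraries, adjusted p = 0.0184, or p = 0.501 with an estimated correlation). Its call was lost without WT vehicle 3 (0.0307), WT 2-DG 2 (0.0436), mutant vehicle 1 (0.0239) or mutant 2-DG 4 (0.0275), with the length and GC correction (0.0207) and with a prefix term (−0.0289).

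Markers of other cells moved with these lists. Neutrophil (median 0.633, 23 of 24 members, 5 of 8 libraries, adjusted p = 0.000523), monocyte (0.337, 17 of 20, 5 of 8, 0.00111), mature red cell (0.152, 13 of 16, 7 of 8, 0.00344) and lymphoid markers (0.326, 17 of 19, 6 of 8, 0.022) were called as higher. So were mitochondrially encoded transcripts (0.0494, 9 of 11, 5 of 8, 0.02), and each of these 5 had an adjusted p = 0.55 with an estimated correlation. Markers of mast cells, basophils and eosinophils were called too (0.335, 8 of 9, 5 of 8, adjusted p = 0.0396, or p = 0.501 with an estimated correlation), with Siglecf (0.54 ± 0.17) higher adjusted over the list alone, the 1 such member in these 6 lists. The neutrophil call was lost without WT vehicle 4 (0.304) or mutant vehicle 1 (0.338), and the median was 0.998 without mutant vehicle 3 and 2.05 with a prefix term. The monocyte call was lost without WT 2-DG 1 (0.13) or mutant 2-DG 3 (0.0738) and with a prefix term (0.235), with medians of 0.203 and 0.539 without WT vehicle 2 and 4 and 0.536 without mutant 2-DG 2. The red cell call was lost without WT 2-DG 2 (0.024) and with a prefix term (0.102). The lymphoid call was lost without WT vehicle 3 or 4 (0.259, 0.127), WT 2-DG 1 or 2 (0.257, 0.233), mutant vehicle 1 or 2 (0.237, 0.188) or mutant 2-DG 1 or 4 (0.273, 0.353), at a filter of 50 (0.294), with array weights (0.284) and with a neutrophil score term (0.165). The lymphoid median was 0.517 without WT vehicle 1, 0.53 without mutant vehicle 3 and 1.38 with a prefix term. The mitochondrial call was lost without WT vehicle 3 or 4 (0.0369, 0.018), WT 2-DG 2 (0.00286), mutant vehicle 1 (0.0388) or mutant 2-DG 1, 2 or 4 (0.0211, 0.0336, 0.04), with a prefix term (0.0717) and with a neutrophil score term (0.0409). Its median was 0.0979 without WT vehicle 1, 0.0759 and 0.0809 without WT 2-DG 1 and 3, 0.0765 without mutant vehicle 3 and 0.12 without mutant 2-DG 3. The mast cell call was lost without WT vehicle 2, 3 or 4 (0.332, 0.31, 0.397), WT 2-DG 1 or 3 (0.283, 0.254), mutant vehicle 2 or 4 (0.288, 0.152) or mutant 2-DG 1 or 3 (0.142, 0.136), with array weights (0.374), the length and GC correction (0.334) or a neutrophil score term (0.176), and the median was 0.846 with a prefix term. In all 18 lists were called as higher and 2 as lower, of which 6 kept their call in each fit without 1 library and 5 with a prefix term, where 1 had the opposite call.

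Across the 15482 tested genes, which are not independent replicates, the 2-DG effects in mutant and in WT cells, which share no library, had a Pearson correlation of 0.325 and a Spearman correlation of 0.364. Among 100 regroupings of the libraries within each genotype, the real one included, 2 gave a Pearson correlation as high, the highest other value was 0.336 and the median −0.00701. The correlation was 0.0948 with a prefix term. The mutant effect under vehicle and the 2-DG effect in mutant cells had a Pearson correlation of −0.339 and a Spearman correlation of −0.3, but they share the mutant vehicle libraries with opposite signs. Simulated unchanged groups gave −0.49, the covariance of −0.0598 differed from the simulated −0.0637 by 0.00396, and with separate mutant vehicle libraries in each effect the 6 splits gave −0.0665 to 0.292 (mean 0.0959). This correlation was −0.0273 with a prefix term.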

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

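The prefix term was fixed beforehand. The other tests of prefix, length and GC content, other cells, JAK-STAT targets and splits here were chosen only after the results were seen.

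Single libraries stood apart from the other 3 of their group in 10 of 135 groups of 4 values tested with Dixon's criterion, which chance alone meets in about 1 in 20 groups, or 6.75 here. Mutant vehicle 1 held 51.91 M reads against 35.94 to 38.32 M, and an Fcgr3 level of 60.0 against 7.49 to 16.4. Mutant vehicle 2 had the highest Cd34 (356 against 74.2 to 85.4) and Podxl (973 against 51.6 to 151) of its group. Mutant vehicle 3 had a lymphoid and plasma cell score of −1.44 against 0.0497 to 0.299. WT vehicle 1 had lower levels of the erythroid regulators Gata1 (14095 against 16470 to 16730) and Klf1 (26821 against 31183 to 31569). Mutant 2-DG 2 had higher Klf1 (31176 against 28180 to 28542) and Arrdc4 (413 against 237 to 262) and a glucose-sensing score of 0.0314 against −0.0695 to −0.0577.

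The 2-DG effects of the genotypes differed by camera's test of the difference itself in 15 lists, and 0 of these kept their call with an estimated correlation. ER chaperones (−0.208) had an adjusted p = 0.181 with an estimated correlation, the N-glycosylation list (−0.0799) an adjusted p = 0.444, neutrophil markers (0.752) an adjusted p = 0.694 and the other 12 lists an adjusted p = 0.674. Over the 15 fits without 1 library the first pair stayed past the threshold at −0.247 to −0.162 and −0.101 to −0.0663. Another 6 lists passed in 14 fits. Of these, immediate early genes (0.561) lost their call at 0.169, G2-M genes (−0.119) at −0.032, S phase genes (−0.109) at −0.058 and mature red cell markers (−0.275) at −0.0127, each without WT 2-DG 1. Interferon-stimulated genes (0.356) lost theirs without WT vehicle 4 (−0.0293) and ribosomal genes (0.0736) without mutant vehicle 2 (0.0241). The interferon median was also 0.595 without WT vehicle 2, 0.214 without WT 2-DG 1, 0.184 and 0.731 without mutant vehicle 1 and 3, and 0.587 without mutant 2-DG 1. Without WT vehicle 4 the S phase, red cell and ribosomal medians were −0.0687, −0.181 and 0.139, the ribosomal median was 0.116 without mutant vehicle 1, and the G2-M median was −0.0764 without WT vehicle 1. Secretion and ER translocation genes (−0.0579) passed in 13, and did not without WT vehicle 3 (−0.0527) or mutant 2-DG 3 (−0.0393). Inflammation and NF-kB genes (0.2) passed in 11, with 0.083, 0.0656, 0.144 and 0.106 in the others (without WT vehicle 4, WT 2-DG 1, mutant vehicle 3 and mutant 2-DG 3). Their median was 0.433, 0.457, 0.131 and 0.304 without WT vehicle 2, WT 2-DG 2, mutant vehicle 4 and mutant 2-DG 1. Heme genes (−0.0811) passed in 10, with −0.0575, 0.0405, −0.0659, −0.0686 and −0.0224 in the others (without WT vehicle 1, WT 2-DG 1, mutant vehicle 1 and 4 and mutant 2-DG 1). Their median was −0.173, −0.166, −0.154, −0.122 and −0.134 without WT vehicle 4, WT 2-DG 2, mutant vehicle 2 and 3 and mutant 2-DG 2. Cholesterol synthesis genes (0.155) passed in 9, with 0.0675, −0.0127, 0.109, 0.0729, 0.092 and 0.117 in the others (without WT vehicle 4, WT 2-DG 1, mutant vehicle 3 and 4, and mutant 2-DG 3 and 4) and 0.244 without mutant 2-DG 2. The neutrophil median passed in 10. It was 0.285, 0.429, 0.0244, 0.434 and 0.443 in the fits where it did not (without WT vehicle 1, mutant vehicle 2 and 3, and mutant 2-DG 1 and 3). It was 1.45, 1.23 and 1.33 without WT vehicle 4, mutant vehicle 1 and mutant 2-DG 2. The monocyte, macrophage and dendritic cell median (0.495) passed in 9, with 0.327, 0.0318, 0.00332, 0.345, 0.453 and 0.162 in the others (without WT vehicle 1 and 4, WT 2-DG 1, mutant vehicle 1 and mutant 2-DG 1 and 3) and 1.03 without mutant 2-DG 2. The median of mitochondrially encoded transcripts (0.0673) passed in 7. It was 0.05, 0.0304, 0.0318, 0.0865, 0.0627, 0.0446, 0.0231 and 0.0704 in the others (without WT vehicle 1 and 2, WT 2-DG 2, mutant vehicle 2 and 3, and mutant 2-DG 1, 2 and 4). It was 0.102, 0.152, 0.17, 0.121, 0.0349 and 0.143 without WT vehicle 3 and 4, WT 2-DG 1 and 3, mutant vehicle 4 and mutant 2-DG 3. With a prefix term the secretion (−0.0558), cholesterol (0.126) and mitochondrial (0.0706) calls were lost, and with array weights the cholesterol (0.0935), heme (−0.0047), inflammation (0.111), red cell (−0.108) and monocyte (−0.00329) calls. Without a sex term the heme (−0.0544), neutrophil (0.418) and mitochondrial (−0.00693) calls were lost. With a neutrophil score term the cholesterol (0.108), monocyte (0.483), neutrophil (0.0176) and mitochondrial (0.0566) calls were, the last also without a filter (0.0528) and with the length and GC correction (0.0272).

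ER chaperones were higher in mutant vehicle and in WT 2-DG cells than in WT vehicle cells (adjusted p = 0.129 and 0.368 with an estimated correlation), in groups that the design separates by mutation and by drug. The tables argue against a trend with transcript length and GC content, since the median in mutant vehicle stayed past the threshold at 0.119 after that correction against 0.122 before. They argue against plasma cells, since the reads of Jchain, Igkc and Mzb1 (25 more per library) made up 0.116% of the list's rise of 21600 reads. For WT 2-DG they argue against the title prefix, with a median of 0.134 with a prefix term and all SX 2-DG libraries above all SX vehicle ones. For the mutant part the median with a prefix term was 0.13, but WT vehicle has only 1 RB and no GG library, so mutation and prefix cannot be told apart. Effects of the mutation and of the drug themselves were not tested further and stay open.

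Cytosolic ribosomal and oxidative phosphorylation genes were lower with 2-DG in both genotypes (each with an adjusted p = 0.287 with an estimated correlation over both), and mitochondrially encoded transcripts, a sign of RNA quality, were lower with them (−0.117 in mutant cells, −0.222 in WT cells and −0.188 over both, adjusted p = 0.319 with an estimated correlation). Against length and GC bias as the whole cause, the medians stayed past the threshold at −0.14 and −0.092 after the correction (−0.179 and −0.119 before). Against the title prefix, the medians with it as a term were −0.204 and −0.158, and both lists were lower within SX, RB and GG. Differences in RNA quality, a shift in the mix of maturation stages, since erythroid genes were lower too, and an effect of 2-DG itself were not tested further and stay open.

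The genes that rose with 2-DG in both genotypes included Trgc1, Socs2, Fam124a, C2cd4a and Podxl. T cells in the sort, which the CD3 and CD5 gates should remove, are argued against as the source of Trgc1, since Cd3d, Cd3e, Cd3g and Trac together rose by 2.47% of its rise (group means at most 14.3), while natural killer cells, marked by Ncr1, were not excluded. Against length and GC bias as the whole cause stand the 99 of 103 called genes with a length. Their median log2 fold was 0.382 after the correction and 0.401 before (median SE 0.0778 both times). Only 13 were still called, with adjusted p-values of up to 0.115 in the others, and why these calls were lost was not tested. Against the title prefix as the whole cause, 100 drawn regroupings, the real one included, that exchanged 2-DG and vehicle only within genotype and prefix gave 103 genes in the real one and at most 28 in the others, but with a prefix term 0 were called (smallest adjusted p 0.0796; median fold 0.383 against 0.401, median SE 0.093 against 0.0793) and the correlation of the 2-DG effects went from 0.325 to 0.0948, so a part played by the prefix stays open. Raised JAK-STAT signalling stays open too: without called genes the fixed target list (22 members, 18 positive, median 0.153) scored higher with 2-DG over both genotypes (exact permutation p = 0.0163), but the score did not pass within mutant (median 0.265, p = 0.0857) or WT cells (median 0.0764, p = 0.257), and other cells also express genes of this list.

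Other splits of the same libraries into groups of the same sizes were fitted in the same way. Any split matches a gene count of 0 (35 of 35 in each single comparison, 100 of 100 drawn for the difference of effects and for the mutant effect over both treatments), so these splits say nothing about chance there. The highest counts of other splits were 41 for mutant against WT under vehicle, 2 and 3 for 2-DG in mutant and in WT cells, and 49 for mutant against WT under 2-DG. They were 741 for the difference of effects and 137 for the mutant effect over both treatments, so the libraries hold a structure that the groups do not follow. The split with 41 genes set the 4 RB libraries against the 3 SX libraries and the GG library, exactly along the title prefix, and within RB the real comparison gave an ER chaperone median of 0.142. For 2-DG over both genotypes chance is less likely for the gene count. The real split gave 103, the highest other 2, and 1 of 100 drawn was as large. These splits did not keep the title prefix, and with a prefix term the count was 0. For the numbers of lists called chance cannot be excluded in mutant against WT under vehicle (12 against a highest other of 19, 14 of 35 splits as large), 2-DG in mutant cells (21 against 23, 3 of 35), and 2-DG in WT cells (15 against 22, 6 of 35). Nor can it in mutant against WT under 2-DG (12 against 21, 18 of 35), the difference of effects (15 against 22, 30 of 100) and 2-DG over both genotypes (21 against 24, 6 of 100). Other splits can carry the shared 2-DG effect in the difference of effects. In the mutant effect over both treatments (20 against 21, 3 of 100) they break the genotype-linked prefix. Both shares decide little.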

How the results depend on the processing

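The length and GC correction, the neutrophil score term and both averaged comparisons were chosen after the data were seen. The other alternatives were planned. No paired analysis was possible, as replicate numbers follow the order of the records and pair no samples. Apart from fits without 1 library, of the gene values 4963 stayed on the same side of the threshold, 227 passed it newly, 95 no longer did and 4 moved; of the list medians 1129 stayed, 1 passed newly, 137 no longer passed, 12 reversed and 3 moved.

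In the planned comparisons limma's 0 calls became, with DESeq2, 2 for mutant against WT under vehicle (Pdia3 and Ncoa4-ps), 235 for 2-DG in mutant cells, 47 for 2-DG in WT cells and 13 for mutant against WT under 2-DG; the simulated reads gave DESeq2 more false calls. For 2-DG in mutant cells 2 were called without a filter (Klra8 among them), 1 with array weights and 2 in a fit of the compared groups alone (Cdkn1a, Aacs). That fit called 1 for 2-DG in WT cells (Irs2) and 5 for mutant against WT under 2-DG (Rpl15-ps6, Mid1, Rpl15-ps2, Gm6937, Zfp960). Without 1 library the counts ranged from 0 to 13 (without mutant vehicle 2) for 2-DG in mutant cells and from 0 to 7 (without WT 2-DG 1) for 2-DG in WT cells. The difference of effects stayed at 0 in each setting. For the mutant effect over both treatments DESeq2 called 30, the fit with a neutrophil score term 2 (G530011O06Rik, Mid1), and fits without 1 library 0 to 7 (without WT vehicle 4). Genes named for these small counts were chosen after their values were seen, and the cause was not tested.

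The 103 genes of 2-DG over both genotypes became 157 at a pseudocount of 5, 296 at a filter of 50, and 163 with TMM scaling. They became 467 without a sex term, 742 with array weights, 1148 with DESeq2 and 158 with a neutrophil score term (87 shared). The count fell to 9 without a filter, 13 with the length and GC correction and 0 with a prefix term. TMM moved the median of all genes by at most 0.0225. Without 1 library the count ranged from 0 to 1108.

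Of the 75 lists called over the planned comparisons, 0 remained with an estimated correlation, and fits without 1 library called 63 to 79. With a prefix term the medians of erythroid and heme genes in mutant against WT under vehicle turned to −0.0276 and −0.00378, and those of interferon-stimulated genes to −0.347 under vehicle and −0.207 over both treatments, both past the threshold as lower, and −0.192 under 2-DG. Over both treatments N-glycosylation and autophagy genes turned to −0.0289 and −0.00887. A neutrophil score term, which removes these markers by construction, turned their own medians to −0.0333 for 2-DG in mutant cells, −0.0188 for mutant against WT under 2-DG and −0.16 for 2-DG over both genotypes. For the difference of effects the mitochondrial median was −0.00693 without a sex term and the monocyte median −0.00329 with array weights. Without 1 library, the medians of the difference of effects ranged from −0.0127 (without WT 2-DG 1) to 0.244 for cholesterol synthesis, from −0.173 to 0.0405 (without WT 2-DG 1) for heme genes and from −0.0293 (without WT vehicle 4) to 0.731 for interferon-stimulated genes. In mutant against WT under vehicle the interferon median ranged from −0.0425 (without mutant vehicle 3) to 0.552 and the neutrophil median from −0.432 to 0.869 (without WT vehicle 4 and mutant vehicle 3). The mitochondrial median of mutant against WT under 2-DG ranged from −0.00337 (without WT 2-DG 2) to 0.169 (without mutant 2-DG 3). The cause was not tested for these other than where stated.

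The correlation of the 2-DG effects, 0.325, was 0.52 at a filter of 50 and 0.0948 with a prefix term, and 0.228 to 0.402 without 1 library. That of the mutant effect with the 2-DG effect in mutant cells, −0.339, was −0.148 at a filter of 50, −0.0273 with a prefix term and −0.497 (without mutant vehicle 2) to −0.242 without 1 library; the cause was not tested. No fit varied the depth.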

Other observations

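The genes singled out in this part were chosen only after their values were seen.

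With 2-DG over both genotypes, autophagy and lysosome genes were lower in 21 of 32 members (median −0.065, camera adjusted p = 0.00582, adjusted p = 0.339 with an estimated correlation, 6 of 7 libraries). Adjusted over the list alone 3 of them were lower and over all genes 0, and the autophagosome protein Map1lc3b (−0.28 ± 0.07) led it. The megakaryocyte and platelet list, the other lineage of these progenitors, did not pass in that comparison (median 0.13, 20 of 30 members higher, adjusted p = 0.584), and ranged from 0.00355 without mutant vehicle 1 to 0.354 without WT 2-DG 1. The iron hormone gene Erfe lay at 84.6 ± 45.3 in WT vehicle, 277 ± 114 in WT 2-DG, 106 ± 58.5 in mutant vehicle and 292 ± 125 in mutant 2-DG, a rise past the threshold.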
